A study of Mus musculus with 8 samples.

How the data were processed

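RNA from primary hepatocytes of wild-type and Hamp knockout mice given CCl4 or olive oil was sequenced in 8 libraries, 2 in each of 4 groups. Hepatocytes were isolated from liver by collagenase digestion in 2 steps and libraries were made by a standard Illumina protocol, per the labels' protocols. The authors deposited a table of FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), per the file headers, with a value for each gene and library rounded to 2 decimals. The build mm8 is given per the submitters' processing notes, and the aligner, the counting tool, the annotation and the number of reads are not given in the sources used here. Each column was assigned to its library by its name and each library to its group by its title. FPKM divides by gene length and by reads mapped in a library, so a gene's value falls where other genes take more reads, and reads shared by near-identical genes could have been divided in ways the table does not show.

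The table held 16338 rows, of which 1 names no gene and was left out, which leaves 16337 genes. Entrez identifiers were matched to the RefSeq annotation of GRCm38.p6, used only for names, neighbours, transcript length and GC content, since it is another build, so no coordinates are given. In it, 99.8% of identifiers were found, 95.9% of those with the same symbol, and 99.73% of tested genes had a transcript length and GC content. Depth could not be recovered from low values. Between the 2 libraries of wild-type oil, 1889 genes had values from 0.15 to 1 FPKM in both, and the fullest bin of 0.05 in the log2 ratio held 170 of them, so no steps of whole reads were seen. The precision of each value is therefore known only from the spread between 2 libraries.

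The choices below were made before the data were examined, apart from those said to have been added. The designed test of read counts was replaced by the one set for normalized values, since the values are FPKM. Values were taken as log2(FPKM + 1), with a pseudocount of 1, and the 10082 genes with at least 1 FPKM in at least 2 libraries were tested, which left out 6255. All 8 libraries were fitted in one model of 4 groups with limma 3.58.1 (trended prior, R 4.3.3), with 4 residual and 2.61 prior degrees of freedom. The 5 contrasts were CCl4 against oil in each genotype, knockout against wild type under each treatment, and the interaction. Benjamini-Hochberg adjustment was made over the genes of each contrast, with an FDR of 0.05. Tests are two-sided. Of 36 gene lists, 32 had at least 5 tested members and were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation and with fry. Counts of members past the threshold are given after adjustment over all genes and adjusted over the list alone.

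Named genes are Hamp, Hamp2, Eif2ak3, Atf4, Ddit3, Hspa5 and Cyp2e1, and up to 4 members of each list with the smallest adjusted p. To these come the 10 largest increases and 10 largest decreases of each contrast among genes past the threshold with mean expression above the median of tested genes and with groups that do not overlap (not asked of the interaction). Symbols that start with Gm and a digit or end in Rik were left out. From these, about 20 to 30 were named per comparison, and genes chosen after their values were seen are said to be so. No fold is given against a group listed at 0.

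Data were simulated with the real mean of each gene in all groups, a pooled spread, independent noise and 200 of 10082 genes changed. At a log2 change of 1 the test recovered 182, 180, 169 and 176 genes, with 13, 2, 10 and 16 false calls. These are for CCl4 in wild type, CCl4 in knockout, genotype in oil and genotype after CCl4, in that order. At a log2 change of 2 it recovered 199 in each. The real data differ from this setting. The SD of the replicate difference was 0.364 and 0.394 in the knockout groups against 0.139 in wild type, replicate differences were shared between the knockout groups, and many more genes changed. The simulation shows only that the fit finds known changes, and gives no error rate for the real fit. The alternatives tried were quantile normalization, no filter on low values, a pseudocount of 0.1, a replicate block, only the 4 libraries compared, a required change of at least 2-fold, an FDR of 0.01, rank correlation, genes above the median expression, and leaving out each library in turn. Added after seeing the data were the removal of GC content and transcript length trends, library weights by genotype, equal library medians, the omission of replicate 2 of both knockout groups, a replicate block in the knockout alone, lists without Hamp and Hamp2, and 4 gene lists. Replicate numbers were used as pairs only in the blocks. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.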

Results

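Gene expression was measured by RNA sequencing in hepatocytes, the metabolic cells of the liver, isolated from wild-type C57BL/6 mice and from mice lacking Hamp, the gene for hepcidin, the liver hormone that limits the release of iron into the blood. Mice had received carbon tetrachloride (CCl4), a solvent that Cyp2e1 converts into a radical that injures hepatocytes, or its carrier, olive oil. The mice were male and 4 weeks old, CCl4 was given as a 12.5% mixture, and exposure lasted 24 h. The study's title names the question as whether hepcidin acts on hepatocyte apoptosis through PERK, the endoplasmic reticulum stress kinase encoded by Eif2ak3. The 4 groups held 2 libraries each, against 6 mice per group in the stated design, and nothing in the labels says whether the 2 libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical. Values were FPKM, and sequencing depth is unknown. Between 8867 and 9384 of the 16337 genes had at least 1 FPKM in a library. The correlation of log2 values across genes between the 2 libraries of a group, which describes libraries and treats no gene as a replicate, was 0.998 in both wild-type groups, 0.982 in the CCl4 knockout group and 0.985 in the oil knockout group. The standard deviation of the difference between the 2 libraries was 0.139 on the log2 scale in both wild-type groups, 0.394 in the CCl4 knockout group and 0.364 in the oil knockout group.

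In the account that follows, fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes, and values after ± are standard errors unless marked as SD. Adjusted p-values are from limma, or from camera for gene lists. For each gene said to have passed the test between 2 groups, both libraries of one group lay on the same side of both libraries of the other. Genes with near-identical copies, among them Saa1 and Saa2, the Mup genes, Cyp2a4 and Cyp2a5, the Cyp2c genes, Hspa1a and Hspa1b, and Hamp and Hamp2, are uncertain as single genes, because reads could have been split between copies.

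Hamp was measured in every library as a check of the labels. The wild-type oil libraries held 1805 and 1826 FPKM and the wild-type CCl4 libraries 1273 and 1136 FPKM. The knockout oil libraries held 2.72 and 0.54 FPKM and the knockout CCl4 libraries 0.98 and 0.83 FPKM. All 4 knockout libraries were therefore far below all 4 wild-type libraries, with log2 fold changes of -9.57 ± 0.36 in oil (adjusted p = 1.71e-05) and -9.30 ± 0.36 after CCl4 (adjusted p = 5.06e-06). The neighbouring and near-identical Hamp2 fell with it, from 192 ± 3.20 FPKM (SD, n = 2) in wild-type oil hepatocytes to 0.13 and 0.23 FPKM in the knockout oil libraries, and it was listed at 0 in both knockout CCl4 libraries. In wild-type hepatocytes, Hamp2 was lower after CCl4 (log2 fold change -1.41 ± 0.09, adjusted p = 0.0002). The log2 difference of Hamp itself, -0.59 ± 0.36, did not pass the test (adjusted p = 0.339). It did without replicate 1 or replicate 2 of the knockout oil group (limma adjusted p = 0.00712 and 0.00717), and with a replicate block in the knockout alone (limma adjusted p = 0.0335).

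**Figure D1:**
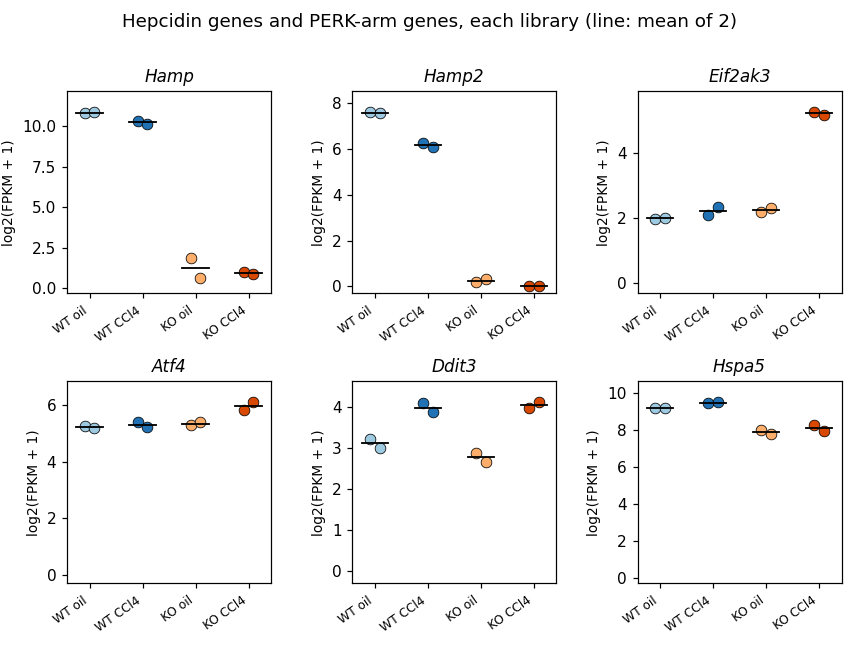
Log2(FPKM + 1) of 6 genes in each of the 8 libraries, with groups along the horizontal axis, points for libraries and a line for the mean of 2 libraries. Hamp and Hamp2 were near the floor in all 4 knockout libraries, and Eif2ak3 stood at 37.54 and 35.41 FPKM in the knockout CCl4 libraries against at most 4.09 FPKM in the other libraries.

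The response of wild-type hepatocytes to CCl4 was taken from the 2 CCl4 and the 2 oil libraries. Cell cycle, cytoskeletal, inflammatory and immediate early genes rose, and genes of cholesterol synthesis fell. Of these lists, only cholesterol synthesis passed with an estimated correlation. Ccnd1, which encodes cyclin D1 and drives entry into the cell cycle, had the largest rise among the named genes, from 0.815 ± 0.106 to 34.0 ± 1.40 FPKM (SD, n = 2 each, log2 fold change 4.27 ± 0.09, adjusted p = 5.59e-06). Nupr1, a stress-induced chromatin protein, followed with 4.18 ± 0.13, and Lgals3 and Lyz2, which encode the macrophage products galectin-3 and lysozyme, with 3.92 ± 0.12 and 3.89 ± 0.18. At the other end, Mup11 and Mup17, which encode major urinary proteins, changed by -5.49 and -4.82, and Selenbp2, a selenium-binding protein gene, fell by 3.85. In limma's test with Benjamini-Hochberg adjustment, 1592 of 10082 genes changed at an FDR of 0.05, of which 1026 were higher and 566 lower after CCl4 (64.4% higher, or 51.8% with quantile normalization), and 305 rose and 78 fell at least 2-fold. This count fell to 596 or 686 without replicate 1 or 2 of the wild-type oil group and to 722 or 645 without replicate 1 or 2 of the wild-type CCl4 group, and it was 3801 with libraries weighted by the spread of their genotype.

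Among the cell cycle genes, 14 of 19 tested members rose and 1 fell. The cell cycle list had 15 higher and 2 lower adjusted over the list alone (camera adjusted p = 4.91e-07, and adjusted p = 0.192 with an estimated correlation). Besides Ccnd1, the members Mcm2, Mcm6 and Mcm3, which encode subunits of the replicative helicase, rose by log2 fold changes of 1.51 ± 0.13, 2.12 ± 0.19 and 1.80 ± 0.17. Of the chemokines and NF-kB targets, 19 of 26 rose. For the chemokine and NF-kB list, camera gave an adjusted p = 1.35e-12, and an adjusted p = 0.115 with an estimated correlation, with 22 higher and 0 lower adjusted over the list alone. They included Cxcl2, a neutrophil-attracting chemokine (3.54 ± 0.14), Il1b, which encodes the cytokine interleukin-1 beta (3.48 ± 0.14), and Ccl2, a monocyte-attracting chemokine, which was listed at 0 in both oil libraries and at 2.5 and 3.32 FPKM in the CCl4 libraries. Of the cytoskeletal genes and YAP targets, 20 of 28 rose, with Vim, an intermediate filament gene, at 2.76 ± 0.12 and Anxa2, which encodes a membrane-binding annexin, at 2.55 ± 0.12. The cytoskeletal and YAP list had 21 higher and 0 lower adjusted over the list alone (camera adjusted p = 7.21e-14, and adjusted p = 0.192 with an estimated correlation). Immediate early genes, which respond within minutes to growth signals and also to tissue digestion, rose in 17 of 21 cases, with Egr1 at 2.46 ± 0.07 and Fos at 2.45 ± 0.09. For the immediate early list, camera gave an adjusted p = 3.55e-12, and an adjusted p = 0.152 with an estimated correlation, with 18 higher and 0 lower adjusted over the list alone. Of the interferon-stimulated genes, 12 of 32 rose, among them Igtp, a GTPase gene (1.29 ± 0.08). The interferon-stimulated list had 12 higher and 0 lower adjusted over the list alone (camera adjusted p = 1.99e-05, and adjusted p = 0.115 with an estimated correlation).

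Of the cholesterol synthesis genes, 19 of 24 fell. For the cholesterol synthesis list, camera gave an adjusted p = 4.16e-19, and an adjusted p = 0.0158 with an estimated correlation, with 0 higher and 22 lower adjusted over the list alone. Msmo1 and Nsdhl, which act in sterol demethylation, changed by log2 fold changes of -2.28 ± 0.07 and -1.79 ± 0.09, and Sqle, the squalene epoxidase gene, by -1.73 ± 0.08. This was the only list of the 32 tested in wild-type hepatocytes that also passed with an estimated correlation. That correlation was estimated from the residuals of all 8 libraries, so the larger spread between knockout replicates enters it too. The P450 and drug metabolism list leaned lower, with 12 of 41 members lower and 5 higher. The P450 list had 6 higher and 14 lower adjusted over the list alone (camera adjusted p = 0.00259, and adjusted p = 0.152 with an estimated correlation). Cyp2e1, the enzyme that activates CCl4, changed by -1.90 ± 0.24 (adjusted p = 0.00280), Cyp2d9 by -1.58 ± 0.09, and Cyp7b1, which hydroxylates oxysterols, by -2.90 ± 0.14. Urea cycle and amino acid genes fell in 12 of 34 cases and rose in 4, with Hal, the histidine ammonia-lyase gene, at -1.10 ± 0.07. For the urea cycle and amino acid list, camera gave an adjusted p = 0.000523, and an adjusted p = 0.429 with an estimated correlation, with 5 higher and 16 lower adjusted over the list alone.

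On the pathway named in the study's title, Eif2ak3 itself did not pass the test in wild-type hepatocytes (log2 difference 0.23 ± 0.11, adjusted p = 0.207), and neither did Atf4, the transcription factor that it induces through translation (0.08 ± 0.12, adjusted p = 0.730). Of the PERK-ATF4-CHOP list, 9 of 27 members rose and 3 fell. The PERK-ATF4-CHOP list had 11 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.00627, and adjusted p = 0.272 with an estimated correlation). Ddit3, which encodes the apoptosis-promoting factor CHOP, rose from 7.72 ± 0.997 to 15.0 ± 1.85 FPKM (SD, n = 2 each, log2 fold change 0.87 ± 0.14, adjusted p = 0.00731). Atf3, a stress-induced transcription factor, rose by 2.20 ± 0.10 and Fgf21, a hormone gene, by 1.22 ± 0.11, while Ddit4, an inhibitor of mTOR signalling, fell by 0.93. The Ddit3 call was lost without replicate 1 of the wild-type CCl4 group (limma adjusted p = 0.0624) or replicate 2 of the wild-type oil group (limma adjusted p = 0.0637). Of the endoplasmic reticulum chaperone genes, 8 of 30 rose, with Hspa5, the main chaperone of that compartment, at 0.29 ± 0.12 (adjusted p = 0.152, not past the threshold, but past it with a replicate block in the knockout alone, limma adjusted p = 0.000419). For the chaperone list, camera gave an adjusted p = 0.000523, and an adjusted p = 0.152 with an estimated correlation, with 13 higher and 1 lower adjusted over the list alone. Of the apoptosis machinery, 1 of 31 members rose and 6 fell, the latter including the pro-apoptotic genes Bik (-1.47 ± 0.13) and Bmf (-0.92 ± 0.09). The apoptosis list had 2 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.107, and adjusted p = 0.397 with an estimated correlation).

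Markers of other liver cells moved in both directions in the same comparison. Any other cells that came with the hepatocytes are part of these libraries. The rises of inflammatory and cytoskeletal genes can therefore not be assigned to hepatocytes alone. Of the Kupffer cell and macrophage markers, 16 of 20 rose, and their share of summed FPKM was 0.0516% and 0.0554% in the wild-type CCl4 libraries against 0.00822% and 0.00943% in the oil libraries. For the macrophage marker list, camera gave an adjusted p = 2.90e-12, and an adjusted p = 0.152 with an estimated correlation, with 16 higher and 0 lower adjusted over the list alone. Of the neutrophil and monocyte markers, 12 of 17 rose, with Chil3, a myeloid lectin gene, at 3.45 ± 0.12 and S100a9, a calcium-binding protein of neutrophils, at 2.94 ± 0.19. The neutrophil and monocyte list had 13 higher and 0 lower adjusted over the list alone (camera adjusted p = 9.03e-08, and adjusted p = 0.115 with an estimated correlation). Of the markers of sinusoidal endothelium, the lining of liver capillaries, 3 of 19 fell and 1 rose. For the endothelial marker list, camera gave an adjusted p = 0.000704, and an adjusted p = 0.429 with an estimated correlation, with 1 higher and 4 lower adjusted over the list alone. Of the hepatocyte markers, 1 of 20 rose and 2 fell. The hepatocyte marker list had 4 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.884, and adjusted p = 0.979 with an estimated correlation).

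The response of Hamp knockout hepatocytes to CCl4 was taken from the 2 CCl4 and the 2 oil libraries of that genotype. Acute phase, cytoskeletal and antioxidant genes rose, and genes of drug metabolism, bile acid handling, lipid synthesis and amino acid breakdown fell. None of the 32 lists set before the data were examined passed with an estimated correlation in this comparison. Members of most lists went both ways. Lcn2, which encodes an iron-sequestering protein of inflammation, rose from 25.9 ± 1.55 to 1771 ± 212 FPKM (SD, n = 2 each, log2 fold change 6.04 ± 0.10, adjusted p = 4.62e-07). Ly6d, a membrane protein gene, was higher as well (5.95 ± 0.13), as was Tubb2a, a tubulin gene (5.21 ± 0.13). Cyp2e1 fell from 3125 ± 133 to 38.7 ± 15.6 FPKM (-6.36 ± 0.24, adjusted p = 3.51e-06), and Cyp8b1, which sets the cholic acid content of bile, and Car3, a carbonic anhydrase gene of mature hepatocytes, changed by -6.24 and -6.02. In limma's test, 5574 of 10082 genes changed, 2816 higher and 2758 lower, and 813 rose and 927 fell at least 2-fold. That is more than the 1592 of the wild type in the model of all 8 libraries, but when only the 4 libraries compared were fitted, the order turned, with 3897 genes in the knockout and 4180 in the wild type. With libraries weighted by the spread of their genotype, the counts were 4289 and 3801.

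Of the acute phase genes, which the liver switches on in inflammation, 25 of 32 rose and 5 fell, with Saa3 at 5.09 ± 0.13, Saa2 at 5.05 ± 0.10, Saa1 at 4.50 ± 0.11 and Apcs, the serum amyloid P gene, at 2.85 ± 0.07. For the acute phase list, camera gave an adjusted p = 5.56e-07, and an adjusted p = 0.237 with an estimated correlation, with 26 higher and 5 lower adjusted over the list alone. Of the cytoskeletal genes and YAP targets, 25 of 28 rose and 1 fell, with Tubb6 at 3.35 ± 0.11 and S100a10 at 3.51 ± 0.12. The cytoskeletal and YAP list had 26 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.59e-12, and adjusted p = 0.237 with an estimated correlation). Of the NRF2 targets, the antioxidant genes, 20 of 32 rose and 6 fell, with Srxn1 at 1.72 ± 0.09 and Gclc, which makes a subunit of the glutathione-forming enzyme, at 1.75 ± 0.11. For the NRF2 target list, camera gave an adjusted p = 0.00895, and an adjusted p = 0.616 with an estimated correlation, with 20 higher and 6 lower adjusted over the list alone. Matrix genes rose in 12 of 16 cases and fell in 1, with Thbs1 at 3.67 ± 0.11. The matrix list had 13 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000760, and adjusted p = 0.106 with an estimated correlation). Chemokines and NF-kB targets rose in 19 of 26 cases and fell in 4, with Ccl2 at 2.47 ± 0.12 and Cxcl1, a neutrophil-attracting chemokine, lower at -2.95 ± 0.12. For the chemokine and NF-kB list, camera gave an adjusted p = 0.000635, and an adjusted p = 0.237 with an estimated correlation, with 19 higher and 4 lower adjusted over the list alone.

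Of the P450 and drug metabolism genes, 30 of 41 fell and 1 rose, and of the genes of pericentral hepatocytes, those around the central vein, 20 of 28 fell and 6 rose. The P450 list had 1 higher and 32 lower adjusted over the list alone (camera adjusted p = 7.88e-09, and adjusted p = 0.0682 with an estimated correlation). For the pericentral list, camera gave an adjusted p = 6.78e-05, and an adjusted p = 0.0682 with an estimated correlation, with 6 higher and 20 lower adjusted over the list alone. Cyp2c54, Cyp2c29 and Cyp2c37 had log2 fold changes of -4.65 ± 0.09, -3.19 ± 0.07 and -4.98 ± 0.11. Of the bile acid genes, 19 of 23 fell and 3 rose, with Baat, which conjugates bile acids, at -3.74 ± 0.07 and Slc10a1, which takes them up from blood, at -2.68 ± 0.07. The bile acid list had 3 higher and 19 lower adjusted over the list alone (camera adjusted p = 4.42e-06, and adjusted p = 0.0682 with an estimated correlation). Lipogenesis genes fell in 18 of 20 cases and rose in 1, with Thrsp, a regulator of lipogenesis, at -4.68 ± 0.09 and Fasn, the fatty acid synthase gene, at -2.89 ± 0.07. For the lipogenesis list, camera gave an adjusted p = 3.00e-07, and an adjusted p = 0.106 with an estimated correlation, with 1 higher and 18 lower adjusted over the list alone. Cholesterol synthesis genes fell in 19 of 24 cases and rose in 2. The cholesterol synthesis list had 2 higher and 19 lower adjusted over the list alone (camera adjusted p = 3.34e-05, and adjusted p = 0.0682 with an estimated correlation). Urea cycle and amino acid genes fell in 25 of 34 cases and rose in 6, with Bhmt, a methionine cycle enzyme gene, at -3.95 ± 0.07 and Hpd, a tyrosine breakdown gene, at -2.68 ± 0.09. For the urea cycle and amino acid list, camera gave an adjusted p = 3.34e-05, and an adjusted p = 0.348 with an estimated correlation, with 7 higher and 26 lower adjusted over the list alone.

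**Figure D2:**
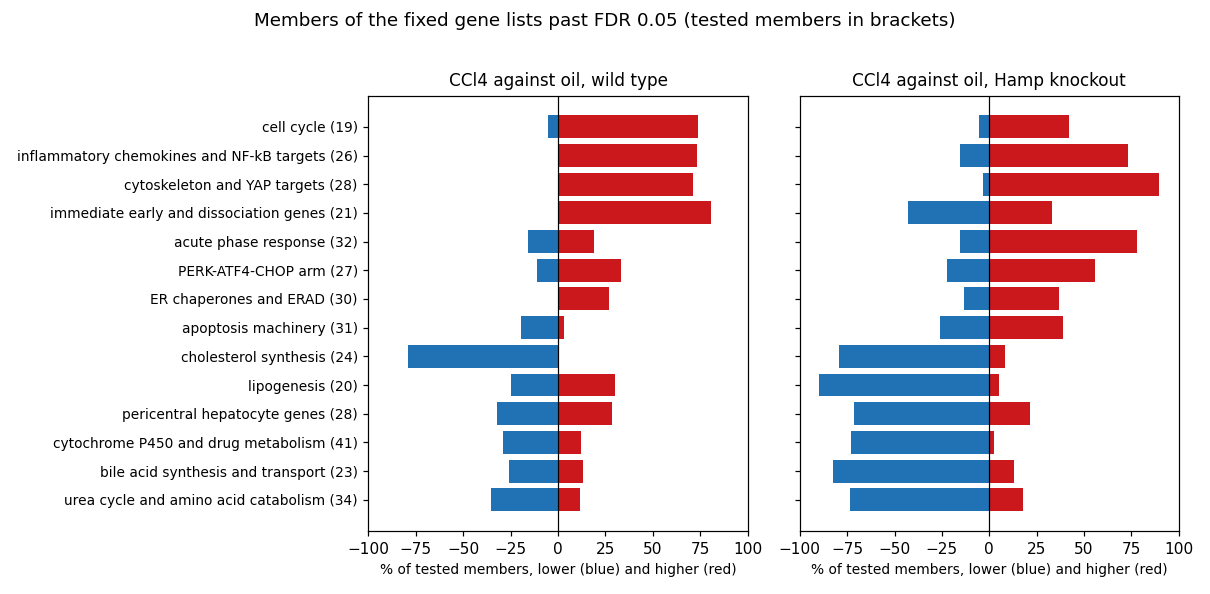
Percentage of the tested members of 14 fixed gene lists that were higher (red, to the right) or lower (blue, to the left) after CCl4 at an FDR of 0.05 in limma's test, in wild-type (left) and Hamp knockout (right) hepatocytes, with the number of tested members in brackets. Of the 41 P450 and drug metabolism genes, 12 were lower in wild-type and 30 in knockout hepatocytes, and of the 24 cholesterol synthesis genes, 19 were lower in each.

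Eif2ak3 rose in knockout hepatocytes from 3.79 ± 0.290 to 36.5 ± 1.51 FPKM (SD, n = 2 each, log2 fold change 2.97 ± 0.11, adjusted p = 3.23e-06). Atf4 rose by 0.62 ± 0.12 (adjusted p = 0.00397) and Ddit3 by 1.28 ± 0.14 (adjusted p = 0.000324). Hspa5 differed by 0.22 ± 0.12 without passing the test (adjusted p = 0.153), but passed without replicate 2 of the knockout CCl4 group (limma adjusted p = 0.0239) and with a replicate block in the knockout alone (limma adjusted p = 0.000846). The PERK-ATF4-CHOP list went both ways, with 15 of 27 members higher and 6 lower, among the latter Cth, the cystathionine gamma-lyase gene (-2.79 ± 0.07), and Ddit4 (-2.40 ± 0.09). The PERK-ATF4-CHOP list had 15 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.0812, and adjusted p = 0.436 with an estimated correlation). Among the apoptosis genes, 12 of 31 rose and 8 fell. For the apoptosis list, camera gave an adjusted p = 0.835, and an adjusted p = 0.920 with an estimated correlation, with 12 higher and 8 lower adjusted over the list alone. The anti-apoptotic Bcl2l1 (2.12 ± 0.11) and the pro-apoptotic Bax (1.62 ± 0.12) were among the higher ones, and the pro-apoptotic Bmf (-1.62 ± 0.09) among the lower. Cdkn1a, the p53 target that arrests the cell cycle, rose by 2.36 ± 0.12, in a list of p53 targets of which 8 of 19 rose and 2 fell. The p53 target list had 8 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.176, and adjusted p = 0.347 with an estimated correlation).

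Neutrophil and monocyte markers rose in knockout hepatocytes in 13 of 17 cases and fell in 1, with Chil3 at 3.87 ± 0.12. For the neutrophil and monocyte list, camera gave an adjusted p = 5.64e-05, and an adjusted p = 0.153 with an estimated correlation, with 13 higher and 1 lower adjusted over the list alone. Macrophage markers rose in 10 of 20 cases and fell in 4, a call that was lost without replicate 2 of the knockout CCl4 group (camera adjusted p = 0.0671) or replicate 1 of the knockout oil group (camera adjusted p = 0.0856). The macrophage marker list had 10 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.0322, and adjusted p = 0.583 with an estimated correlation). Of the endothelial markers, 12 of 19 fell, with Ehd3 at -1.98 ± 0.10. For the endothelial marker list, camera gave an adjusted p = 0.00143, and an adjusted p = 0.447 with an estimated correlation, with 0 higher and 12 lower adjusted over the list alone. With neutrophil and monocyte markers higher, the rises of inflammatory and cytoskeletal genes cannot be assigned to hepatocytes alone here either.

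**Figure D3:**
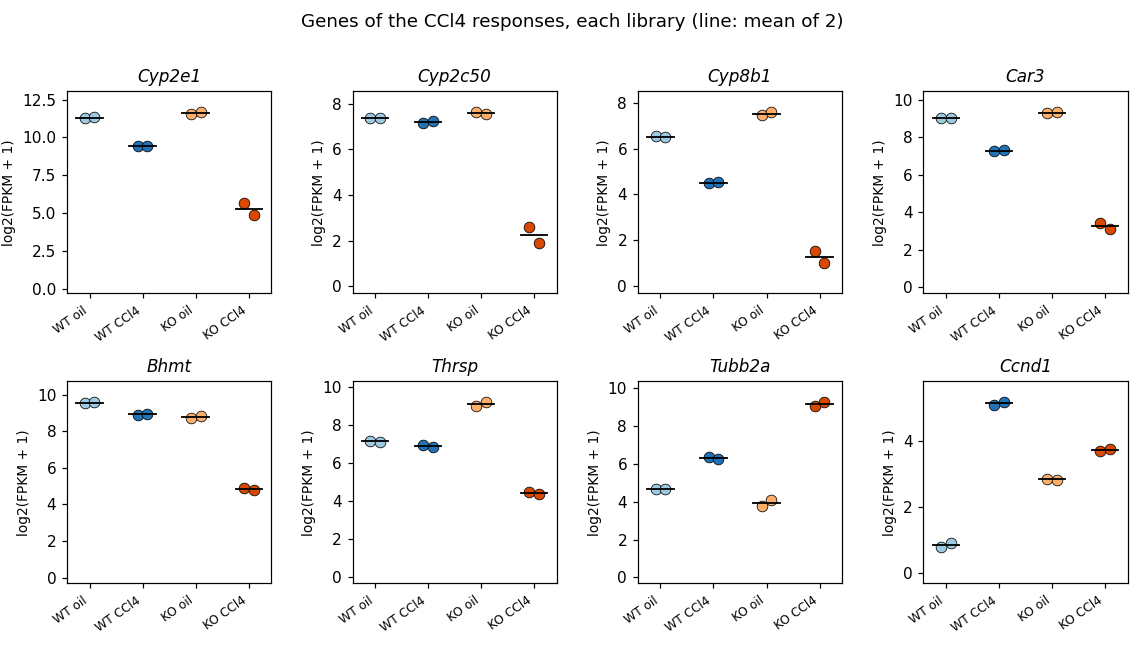
Log2(FPKM + 1) of 8 genes in each of the 8 libraries, with groups along the horizontal axis, points for libraries and a line for the mean of 2 libraries. Cyp2e1, Cyp2c50, Cyp8b1, Car3, Bhmt and Thrsp were lowest in both knockout CCl4 libraries, Tubb2a was highest there, and Ccnd1 was highest in both wild-type CCl4 libraries.

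Hepatocytes of oil-treated knockout and wild-type mice were compared to see how the genotypes differed without CCl4. Acute phase and endoplasmic reticulum chaperone genes were lower in knockout hepatocytes, and immediate early, fatty acid oxidation, lipogenesis, macrophage and endothelial genes were higher. Again, none of the 32 lists set before the data were examined passed with an estimated correlation. Besides Hamp and Hamp2, the largest decrease among the named genes was that of Saa2, an acute phase apolipoprotein gene, from 23504 ± 829.5 FPKM in wild-type to 225 ± 1.04 FPKM in knockout hepatocytes (SD, n = 2 each, log2 fold change -6.70 ± 0.10, adjusted p = 4.46e-07). Next came Lcn2 (-6.11 ± 0.10), Saa1 (-5.89 ± 0.11) and Orm2, which encodes orosomucoid (-5.66 ± 0.11). The largest increase of a single gene was that of Cyp2a4, a steroid hydroxylase gene (9.20 ± 0.20). Its sum with the near-identical Cyp2a5 differed less, from 159.2 to 2166 FPKM. Cyp2a4 is the female-predominant copy, and the share of Y-linked genes in summed FPKM was lower in the knockout. A difference in sex was therefore not told apart from genotype here. Other large increases were those of Fos (5.13 ± 0.09), Cyp2c40 (4.95 ± 0.23), Ppp1r3g, which directs glycogen synthesis (4.92 ± 0.14), and Egr1 (4.50 ± 0.07). Scd1, the stearoyl-CoA desaturase gene, differed from 73.9 ± 1.91 to 1139 ± 20.2 FPKM (3.93 ± 0.06, adjusted p = 4.85e-07). In limma's test, 3368 of 10082 genes differed, 2256 higher and 1112 lower in the knockout (67.0% higher, or 56.4% with quantile normalization), and 456 were at least 2-fold higher and 221 at least 2-fold lower. The count was 1650 or 1744 without replicate 1 or 2 of the wild-type oil group, and 5125 without replicate 2 of both knockout groups.

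Of the acute phase genes, 25 of 32 were lower and 3 higher. The acute phase list had 3 higher and 26 lower adjusted over the list alone (camera adjusted p = 3.26e-15, and adjusted p = 0.187 with an estimated correlation). Their share of summed FPKM was 17.9% and 18.4% in the wild-type oil libraries and 4.27% and 4.34% in the knockout oil libraries. In the wild-type CCl4 libraries it was 18.5% and 18.4%, so oil-treated wild-type hepatocytes already stood near the level seen after CCl4. They were therefore not a baseline of low acute phase expression, and the cause was not tested. Of the endoplasmic reticulum chaperone genes, 19 of 30 were lower and 2 higher. For the chaperone list, camera gave an adjusted p = 2.19e-10, and an adjusted p = 0.123 with an estimated correlation, with 2 higher and 19 lower adjusted over the list alone. Hspa5 stood at 585 ± 6.92 FPKM in wild-type and 234 ± 23.3 FPKM in knockout hepatocytes (SD, n = 2 each, log2 fold change -1.32 ± 0.12, adjusted p = 0.000391), and Creld2 (-1.93 ± 0.08) and Sdf2l1 (-2.41 ± 0.14) were lower as well. Eif2ak3 (0.26 ± 0.11, adjusted p = 0.111), Atf4 (0.12 ± 0.12, adjusted p = 0.473) and Ddit3 (-0.34 ± 0.14, adjusted p = 0.107) did not pass the test between genotypes in oil. With a replicate block in the knockout alone, Eif2ak3 and Ddit3 did (limma adjusted p = 0.037 and 0.0283). Of the PERK-ATF4-CHOP list, 15 of 27 members were higher and 1 lower. Higher members included Ddit4 (3.20 ± 0.09), Atf3 (1.88 ± 0.10) and Ppp1r15a, which encodes a phosphatase subunit that reverses PERK signalling (1.46 ± 0.08). The PERK-ATF4-CHOP list had 15 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000518, and adjusted p = 0.193 with an estimated correlation). Of the apoptosis genes, 4 of 31 were higher and 5 lower. For the apoptosis list, camera gave an adjusted p = 0.267, and an adjusted p = 0.478 with an estimated correlation, with 4 higher and 5 lower adjusted over the list alone.

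The lists of lipid metabolism went both ways in oil-treated knockout hepatocytes. Of the genes of fatty acid oxidation and PPARA targets, 27 of 34 were higher and 3 lower, with Fabp1, a fatty acid-binding protein gene, at 2.30 ± 0.08 and Acot1, an acyl-CoA thioesterase gene, at 3.03 ± 0.13. The fatty acid oxidation list had 27 higher and 3 lower adjusted over the list alone (camera adjusted p = 2.86e-08, and adjusted p = 0.187 with an estimated correlation). Of the lipogenesis genes, 15 of 20 were higher and 4 lower, with Pklr, the liver pyruvate kinase gene, at 3.04 ± 0.07 and Elovl5, a fatty acid elongase gene, at 2.28 ± 0.06. For the lipogenesis list, camera gave an adjusted p = 0.000121, and an adjusted p = 0.187 with an estimated correlation, with 15 higher and 4 lower adjusted over the list alone. Of the cholesterol synthesis genes, 10 of 24 were lower and 3 higher. The cholesterol synthesis list had 3 higher and 11 lower adjusted over the list alone (camera adjusted p = 0.0254, and adjusted p = 0.187 with an estimated correlation). In the iron handling list, 6 of 28 were lower, Hamp and Hamp2 among them, and 4 higher. For the iron handling list, camera gave an adjusted p = 0.0499, and an adjusted p = 0.365 with an estimated correlation, with 4 higher and 6 lower adjusted over the list alone. Hamp is the gene the knockout is named for, and the labels do not say whether the deletion reaches Hamp2. Without both, the list did not pass (camera adjusted p = 0.278, and adjusted p = 0.597 with an estimated correlation). Of the 26 members left, 4 were lower and 4 higher. The call of the whole list was also lost under 10 other alternatives, among them leaving out any 1 library except replicate 1 of the wild-type oil group and replicate 2 of the knockout oil group (camera adjusted p from 0.0511 to 0.0773). Besides Hamp and Hamp2, the lower members included Hp (-2.46 ± 0.11) and Hpx (-1.62 ± 0.11), which encode the scavengers of hemoglobin and heme and are acute phase genes too. Among the BMP-SMAD targets, the pathway that controls Hamp, Id2 (-2.05 ± 0.09) and Id3 (-1.57 ± 0.13) were lower and Id1 (0.60 ± 0.10) was higher, and the list, which includes Hamp, did not pass, with 1 of 8 higher and 3 lower. The BMP-SMAD list had 2 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0706, and adjusted p = 0.396 with an estimated correlation).

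Immediate early genes were higher in 21 of 21 cases in knockout oil hepatocytes, with Jun at 2.47 ± 0.09. For the immediate early list, camera gave an adjusted p = 2.43e-14, and an adjusted p = 0.187 with an estimated correlation, with 21 higher and 0 lower adjusted over the list alone. Macrophage markers were higher in 18 of 20 cases, with Adgre1 at 2.92 ± 0.10 and Cd5l at 3.62 ± 0.17, and endothelial markers in 19 of 19 cases, with Stab2 at 2.13 ± 0.09. The macrophage marker list had 18 higher and 0 lower adjusted over the list alone (camera adjusted p = 6.75e-12, and adjusted p = 0.187 with an estimated correlation). For the endothelial marker list, camera gave an adjusted p = 3.35e-12, and an adjusted p = 0.193 with an estimated correlation, with 19 higher and 0 lower adjusted over the list alone. The macrophage share of summed FPKM was 0.0730% and 0.0889% in the knockout oil libraries against 0.00822% and 0.00943% in the wild-type oil libraries, and the endothelial share 0.0199% and 0.0240% against 0.00318% and 0.00389%. Stellate cell markers were higher in 4 of 6 cases. The stellate cell marker list had 5 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00409, and adjusted p = 0.187 with an estimated correlation). Neutrophil and monocyte markers were higher in 4 of 17 cases and lower in 2. For the neutrophil and monocyte list, camera gave an adjusted p = 0.790, and an adjusted p = 0.945 with an estimated correlation, with 5 higher and 2 lower adjusted over the list alone.

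**Figure D4:**
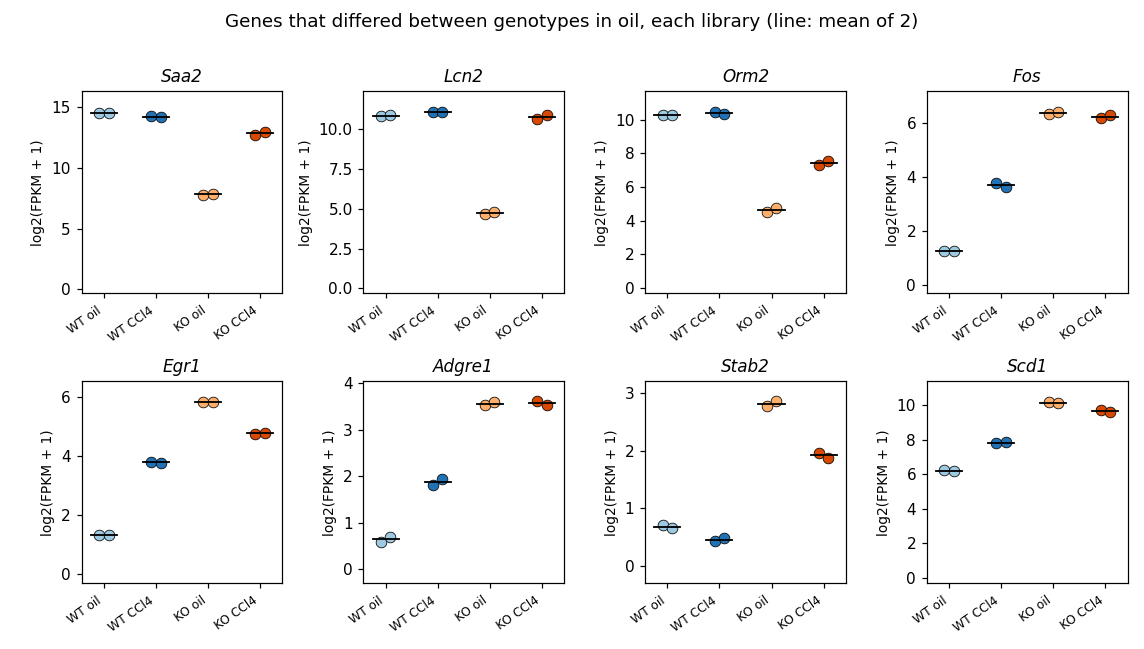
Log2(FPKM + 1) of 8 genes in each of the 8 libraries, with groups along the horizontal axis, points for libraries and a line for the mean of 2 libraries. Saa2, Lcn2 and Orm2 were lowest in both knockout oil libraries, and Fos, Egr1, Stab2 and Scd1 were highest there, while Adgre1 was higher in the 4 knockout libraries than in the 4 wild-type libraries.

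After CCl4, knockout and wild-type hepatocytes differed in 57.1% of the genes tested. Genes of bile acid handling, pericentral identity, urea and amino acid metabolism and endoplasmic reticulum chaperones were lower in the knockout, and cytoskeletal, matrix, macrophage and endothelial genes were higher, all by the preset correlation and none with an estimated one. With markers of other cells higher, the higher cytoskeletal and matrix genes cannot be assigned to hepatocytes alone. Cyp2a5 (6.52 ± 0.09) and Cyp2a4 (6.18 ± 0.20) had the largest increases among the named genes, followed by Pdk4, which restrains glucose oxidation (5.68 ± 0.12), and Ppp1r3g (5.39 ± 0.14). Igfbp1, which encodes a binding protein of insulin-like growth factors, differed from 91.1 ± 0.643 to 2257 ± 259 FPKM (SD, n = 2 each, log2 fold change 4.61 ± 0.10, adjusted p = 9.60e-07). Besides Hamp and Hamp2, the largest decreases were those of Cyp26a1, which degrades retinoic acid (-5.61 ± 0.11), Apol7a (-5.11 ± 0.10), Cyp2c50 (-4.96 ± 0.20) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-4.82 ± 0.30, adjusted p = 3.84e-05). In limma's test, 5761 of 10082 genes differed, 2989 higher and 2772 lower in the knockout, and 775 were at least 2-fold higher and 956 at least 2-fold lower.

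Eif2ak3 was higher in knockout CCl4 hepatocytes, at 36.5 ± 1.51 FPKM against 3.71 ± 0.537 FPKM in wild-type CCl4 hepatocytes (SD, n = 2 each, adjusted p = 4.15e-06). Atf4 was higher by 0.65 ± 0.12 (adjusted p = 0.00337), Ddit3 did not pass the test (0.07 ± 0.14, adjusted p = 0.689) and Hspa5 was lower (-1.39 ± 0.12, adjusted p = 0.000127). Of the PERK-ATF4-CHOP list, 17 of 27 members were higher and 4 lower, with Gdf15, a stress cytokine gene, at 2.95 ± 0.15 and Cth at -2.99 ± 0.07. The PERK-ATF4-CHOP list had 17 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.00214, and adjusted p = 0.233 with an estimated correlation). Of the chaperone genes, 20 of 30 were lower and 2 higher, with Creld2 at -2.09 ± 0.08 and Hyou1 at -1.47 ± 0.08. For the chaperone list, camera gave an adjusted p = 4.37e-06, and an adjusted p = 0.116 with an estimated correlation, with 2 higher and 21 lower adjusted over the list alone. Apoptosis genes were higher in 12 and lower in 12 of 31 cases. The apoptosis list had 12 higher and 12 lower adjusted over the list alone (camera adjusted p = 0.919, and adjusted p = 0.949 with an estimated correlation). Higher members included Bcl2l1 (2.16 ± 0.11) and Bax (1.49 ± 0.12), and a lower member was Bik (-0.78 ± 0.13).

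Bile acid genes were lower in 19 of 23 cases and higher in 2, with Baat at -3.33 ± 0.07. For the bile acid list, camera gave an adjusted p = 2.78e-06, and an adjusted p = 0.113 with an estimated correlation, with 2 higher and 19 lower adjusted over the list alone. Pericentral genes were lower in 20 of 28 cases and higher in 5, with Cyp2c54 at -4.72 ± 0.09, Car3 at -4.01 ± 0.10 and Cyp2e1 at -4.17 ± 0.24. The pericentral list had 5 higher and 20 lower adjusted over the list alone (camera adjusted p = 3.01e-05, and adjusted p = 0.113 with an estimated correlation). Urea cycle and amino acid genes were lower in 26 of 34 cases and higher in 5, with Bhmt at -4.08 ± 0.07 and Hpd at -3.13 ± 0.09. For the urea cycle and amino acid list, camera gave an adjusted p = 3.29e-05, and an adjusted p = 0.331 with an estimated correlation, with 6 higher and 26 lower adjusted over the list alone. Of the genes of fatty acid oxidation, 20 of 34 were higher and 7 lower, led by Pdk4. The fatty acid oxidation list had 20 higher and 7 lower adjusted over the list alone (camera adjusted p = 0.00111, and adjusted p = 0.233 with an estimated correlation). Cytoskeletal genes and YAP targets were higher in 26 of 28 cases, with Anxa5 at 2.75 ± 0.08 and S100a10 at 2.95 ± 0.12, and matrix genes in 11 of 16 cases. For the cytoskeletal and YAP list, camera gave an adjusted p = 1.61e-08, and an adjusted p = 0.233 with an estimated correlation, with 26 higher and 0 lower adjusted over the list alone. The matrix list had 11 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00152, and adjusted p = 0.144 with an estimated correlation). Macrophage markers were higher in 16 of 20 cases, endothelial markers in 18 of 19 and stellate cell markers in 6 of 6, with Sparc at 1.99 ± 0.10. For the macrophage marker list, camera gave an adjusted p = 2.78e-06, and an adjusted p = 0.233 with an estimated correlation, with 16 higher and 0 lower adjusted over the list alone. The endothelial marker list had 19 higher and 0 lower adjusted over the list alone (camera adjusted p = 1.82e-07, and adjusted p = 0.233 with an estimated correlation). For the stellate cell marker list, camera gave an adjusted p = 0.00212, and an adjusted p = 0.144 with an estimated correlation, with 6 higher and 0 lower adjusted over the list alone. The macrophage share of summed FPKM was 0.121% and 0.138% in the knockout CCl4 libraries against 0.0516% and 0.0554% in the wild-type CCl4 libraries.

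Whether the response to CCl4 itself differed between genotypes was tested by the interaction of genotype and treatment, in which a positive value means a larger rise, or a smaller fall, in the knockout. Acute phase and cytoskeletal genes responded more positively in knockout hepatocytes, and genes of drug metabolism, bile acids, lipogenesis and immediate early response more negatively. These calls hold at the preset correlation, and no interaction list passed with an estimated one. Eif2ak3 had an interaction log2 fold change of 2.74 ± 0.15 (adjusted p = 5.48e-05), Atf4 of 0.53 ± 0.16 (adjusted p = 0.0465) and Cyp2e1 of -4.46 ± 0.33 (adjusted p = 0.000193). Ddit3 (0.41 ± 0.19, adjusted p = 0.157) and Hspa5 (-0.07 ± 0.16, adjusted p = 0.785) did not pass. The Atf4 call was lost without any 1 of 7 libraries (limma adjusted p from 0.0549 to 0.157) and held only without replicate 1 of the knockout CCl4 group. In limma's test, 3355 of 10082 genes had an interaction, 1437 positive and 1918 negative (42.8% positive, or 53.1% with quantile normalization). Of these, 2464 changed past the threshold only in the knockout, 423 changed the same way in both genotypes with a larger size in the knockout, 81 with a smaller size, 157 changed in opposite directions, 141 passed only in the wild type and 89 in neither. This division rests on the wild-type calls of the model of all 8 libraries, and 777 of the 2464 passed in the wild type too when only its 4 libraries were fitted. The count was 2154 or 2063 without replicate 1 or 2 of the wild-type CCl4 group, 2056 or 2007 without replicate 1 or 2 of the wild-type oil group, and 5241 without replicate 2 of both knockout groups.

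Of the acute phase genes, 24 of 32 had a positive and 4 a negative interaction. The acute phase list had 24 positive and 4 negative adjusted over the list alone (camera adjusted p = 8.72e-09, and adjusted p = 0.220 with an estimated correlation). Their starting levels in oil differed between genotypes, and Saa2 stood at 19196 ± 867 FPKM in wild-type and 7475 ± 838 FPKM in knockout hepatocytes after CCl4 (SD, n = 2 each). Cytoskeletal genes were positive in 18 of 28 cases and negative in 3. For the cytoskeletal and YAP list, camera gave an adjusted p = 6.14e-07, and an adjusted p = 0.495 with an estimated correlation, with 18 positive and 3 negative adjusted over the list alone. P450 genes were negative in 26 of 41 cases and positive in 1, pericentral genes negative in 19 of 28 and positive in 2, and bile acid genes negative in 17 of 23 and positive in 4. The P450 list had 1 positive and 31 negative adjusted over the list alone (camera adjusted p = 2.58e-08, and adjusted p = 0.0633 with an estimated correlation). For the pericentral list, camera gave an adjusted p = 6.14e-07, and an adjusted p = 0.0633 with an estimated correlation, with 3 positive and 21 negative adjusted over the list alone. The bile acid list had 4 positive and 18 negative adjusted over the list alone (camera adjusted p = 7.26e-06, and adjusted p = 0.0633 with an estimated correlation). Lipogenesis genes were negative in 15 of 20 cases and positive in 1, with Thrsp at -4.44 ± 0.13 and Scd1 at -2.09 ± 0.09. For the lipogenesis list, camera gave an adjusted p = 3.59e-07, and an adjusted p = 0.162 with an estimated correlation, with 2 positive and 16 negative adjusted over the list alone. Immediate early genes were negative in 15 of 21 cases and positive in 3, with Egr1 at -3.51 ± 0.10, and cell cycle genes negative in 12 of 19 cases and positive in 1, with Ccnd1 at -3.39 ± 0.12. The immediate early list had 3 positive and 16 negative adjusted over the list alone (camera adjusted p = 0.000161, and adjusted p = 0.495 with an estimated correlation). These genes started higher in knockout oil hepatocytes in 21 of 21 cases. After CCl4, 19 of 21 were still higher in the knockout and 2 lower (camera adjusted p = 4.37e-06, and adjusted p = 0.233 with an estimated correlation). In the knockout response to CCl4, 7 rose and 9 fell (camera adjusted p = 0.568). The negative interaction thus went with the higher start in oil. For the cell cycle list, camera gave an adjusted p = 0.00248, and an adjusted p = 0.506 with an estimated correlation, with 1 positive and 13 negative adjusted over the list alone. Macrophage markers were negative in 10 of 20 cases and positive in 0, and endothelial markers negative in 5 of 19 and positive in 0. The macrophage marker list had 0 positive and 14 negative adjusted over the list alone (camera adjusted p = 0.00226, and adjusted p = 0.592 with an estimated correlation). For the endothelial marker list, camera gave an adjusted p = 0.0713, and an adjusted p = 0.721 with an estimated correlation, with 0 positive and 5 negative adjusted over the list alone. The PERK-ATF4-CHOP list had 4 positive and 6 negative members of 27, and the apoptosis list 9 positive and 6 negative members of 31. The PERK-ATF4-CHOP list had 4 positive and 6 negative adjusted over the list alone (camera adjusted p = 0.924, and adjusted p = 0.962 with an estimated correlation). For the apoptosis list, camera gave an adjusted p = 0.261, and an adjusted p = 0.603 with an estimated correlation, with 10 positive and 6 negative adjusted over the list alone.

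Across the 10082 genes, which are not independent replicates, the log2 fold changes of the 2 genotypes after CCl4 correlated with a Pearson r of 0.493 and a Spearman rho of 0.441, with no library shared between the 2 comparisons. Both responses were higher for 746 genes, where independent lists would share 286.6, and both lower for 426, where independent lists would share 154.8, and 157 genes changed in opposite directions. The differences between genotypes in oil and after CCl4 correlated with a Pearson r of 0.499, with 1272 genes higher in both (668.8 for independent lists), 693 lower in both (305.7) and 473 in opposite directions.

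**Figure D5:**
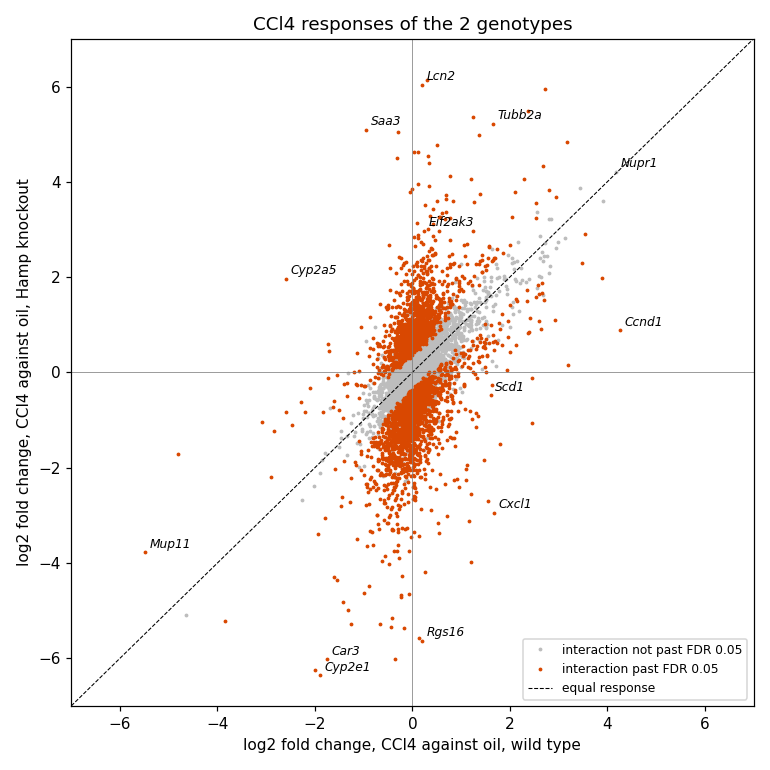
Log2 fold change after CCl4 in wild-type (horizontal) and Hamp knockout (vertical) hepatocytes for the 10082 tested genes, with the 3355 genes past an FDR of 0.05 for the interaction in orange and the line of equal response dashed. Eif2ak3, Saa3 and Lcn2 lay above the line, and Cyp2e1, Car3, Rgs16 and Cxcl1 below it.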

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

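Of the tests weighed here, those of cell shares, of separate occasions, of the genes next to Eif2ak3 and of the whole PERK arm were chosen only after the result was seen. The removal of GC content and transcript length trends was also added after the data were seen.

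The responses of the 2 genotypes to CCl4 differed for 3355 genes in limma's test of the interaction of genotype and treatment, and the named genes below were marked by that test, with a positive log2 value for a more positive response in knockout hepatocytes. In the set named before the data were examined, these were Eif2ak3 (2.74), Atf4 (0.53) and Cyp2e1 (-4.46), of which the Atf4 call was lost without any 1 of 7 libraries. The most positive interactions were those of the acute phase genes Saa3 (6.04), Lcn2 (5.84), Saa2 (5.34) and Saa1 (4.81), followed by Cyp2a5 (4.57, but 2.63 for its sum with the near-identical Cyp2a4), the claudin gene Cldn14 (3.85), Tnfrsf12a (3.63), which encodes the receptor of TWEAK, Tubb2a (3.57), the steroid hydroxylase gene Cyp17a1 (3.34) and S100a10 (3.24). The most negative were those of Rgs16 (-5.84), a regulator of G protein signalling, Serpina6 (-5.71), which encodes corticosteroid-binding globulin, Inmt (-5.67), Elovl6 (-5.19), a fatty acid elongase gene, Cyp2c50 (-5.18), Hsd3b3 (-4.90), Nrep (-4.75), Cxcl1 (-4.62), Akr1d1 (-4.61), a bile acid reductase gene, and Cyp2c54 (-4.58).

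In oil, knockout hepatocytes had lower acute phase genes and higher macrophage, endothelial and immediate early genes than wild-type hepatocytes. For the acute phase genes, GC content or transcript length is argued against. The median log2 fold change of the 25 called lower in this fit was -1.62, and -1.70 once those trends were removed from each library. The macrophage, endothelial and immediate early lists also kept their camera calls at the preset correlation once the trends were removed. No median without the trends is given for them. A lower share of hepatocytes that raised the markers of every other cell type alike is argued against too. The macrophage, endothelial and stellate cell medians were 2.43, 1.79 and 0.94 and the neutrophil median 0.05, a gap of 2.38. These medians cannot decide on an unequal carry-over of macrophages, endothelial and stellate cells. Such a carry-over stays open and would not be a change within hepatocytes. Livers of the 2 genotypes digested or collected on separate occasions cannot be told apart from the genotype, since all 21 immediate early genes tested were higher in the knockout and no collection dates are given in the sources used here. Loss of Hamp, which the design names, stays open as well, and was not tested apart from such an occasion.

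Replicate 1 and replicate 2 differed along a shared axis in the knockout groups, where the differences between replicates of the oil and CCl4 groups correlated across genes with r = 0.80. Removing the trends with GC content and transcript length lowered this to 0.64, so such a trend could account for part of the axis, and the rest stays open. A different share of macrophages and endothelial cells in replicate 2 cannot be told apart from other causes either. The median of replicate 1 minus replicate 2 was -0.30 for the macrophage markers and -0.17 for the endothelial markers, so both were higher in replicate 2. The Y-linked share of summed FPKM was instead lower in replicate 2, at 0.000569% against 0.00177% after CCl4 and 0.00103% against 0.00377% in oil. In all 4 knockout libraries it lay below the wild-type range of 0.00414% to 0.00496%, although all mice are stated to be male. A difference in the sex of the mice or a mislabelled library was not tested. A difference in sex cannot be told apart from genotype in the comparisons of genotypes. The design names no group that differs along this axis, so no biological explanation was tested.

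Eif2ak3 stood at least 8-fold higher in FPKM in both knockout CCl4 libraries than in each of the other 6 libraries, as did 1 other gene, Btg3, named here after its values were seen, of the 2038 genes between 2 and 8 FPKM in those 6. These bounds were not among the choices made before the data were examined, so the count gives no measure of rarity. GC content and transcript length are argued against, as its interaction log2 fold change was 2.74 before and 2.77 after those trends were removed. Reads running on from the nearest listed genes are argued against too, as the higher of them, Rpia, stood at 6.35 FPKM against 36.5 for Eif2ak3, and the more distant Fabp1, at 8876 FPKM, stood at 8039 FPKM in knockout oil, where Eif2ak3 was at 3.79. Rpia itself rose in the same group alone, from 1.80, 1.18 and 1.55 FPKM in the others, so a change shared by this region stays open. A rise of the whole PERK arm in the interaction by about that of Eif2ak3 is argued against. The other 26 members had a median interaction of -0.13 (median absolute deviation 0.85). The interaction cancels a difference present under both treatments, so it cannot decide on one. The list leaned higher in the knockout in oil (median 0.72, 15 of 27 higher and 1 lower) and after CCl4 (median 0.89, 17 higher and 4 lower). A smaller rise of part of the arm (3 of the 9 others called were positive) and a response of Eif2ak3 itself that depends on the genotype stay open. Both are hypotheses found and tested on the same data.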

How the results depend on the processing

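Removal of GC content and transcript length trends, library weights, equal library medians, the omission of replicate 2 of both knockout groups, a block in the knockout alone and lists without Hamp and Hamp2 were chosen after seeing the data, and the other alternatives before the data were examined. Over 17 alternatives, 2770 of 2805 values of 165 named gene results kept their direction and side of the threshold, 12 lost the call, 15 gained it and 8 turned direction. Most of these genes were picked from the main fit for large changes or small adjusted p, and some settings cannot move some estimates. High agreement was therefore largely fixed in advance. Over all genes, quantile normalization kept 1267 of the 1592 wild-type calls and 2688 of the 3368 genotype calls in oil. Over 19 alternatives, 1331 of 1463 values of the 77 list results that passed kept their call, and 76 of the 132 losses came with the estimated correlation. The genes that turned direction had not passed the test, and the cause was not tested. Atf4 between genotypes in oil was -0.0061 with quantile normalization. Ddit3 between genotypes after CCl4 was -0.0078 without replicate 2 of both knockout groups, and -0.0495 to 0.187 without single libraries. Hspa5 for the interaction was 0.0456 with trends removed and 0.0078 with equal medians, and -0.22 to 0.082 without single libraries. Counts of changed genes ranged, when single libraries were left out, from 596 to 1954 for CCl4 in wild type, 4677 to 5649 for CCl4 in knockout, 1650 to 3919 for genotype in oil, 4015 to 6312 for genotype after CCl4 and 2007 to 3892 for the interaction. A group left with 1 library was assumed to vary like the others. The wild-type count was 2518 with trends removed, 3801 with library weights and 4180 with only the 4 libraries compared (3897 in knockout), and without replicate 2 of both knockout groups the wild-type, oil and interaction counts were 4167, 5125 and 5241. With a change of at least 2-fold required, the counts in the same order were 383, 1740, 677, 1731 and 1269, and at an FDR of 0.01 the wild-type, oil and interaction counts were 782, 1863 and 1844, as stricter thresholds must give. Of the 32 lists, 16, 15, 14, 19 and 13 passed in the same order, 1, 0, 0, 0 and 0 with camera's estimated correlation, and 27, 26, 30 and 21 with fry in the last 4, which asks a different question. Leaving out single libraries gave 14 to 17, 14 to 16, 11 to 19, 16 to 22 and 11 to 13. The log2 fold change of Hamp ranged from -10.20 to -8.93 in oil and from -9.39 to -9.22 after CCl4. The correlation of the 2 CCl4 responses was 0.473 with quantile normalization, 0.451 in genes above the median expression and 0.441 by rank, and 0.462 to 0.502 without single libraries. With the replicate block the counts were 1617, 5727, 3568, 6094 and 3517. The interaction calls of Atf4 (limma adjusted p = 0.0525) and of the matrix list (camera adjusted p = 0.0583) were lost. So was the call of the iron handling list between genotypes in oil (camera adjusted p = 0.0553). The differences between replicates correlated at 0.80 between the knockout groups and between -0.25 and 0.22 elsewhere, and nothing in the labels says what a number shares. With a replicate block in the knockout alone, the counts were 3973, 7409, 6067, 7705 and 5876, and the cell cycle list after CCl4 (camera adjusted p = 0.0791) and the matrix list for the interaction (camera adjusted p = 0.161) did not pass. Hamp in wild type, Hspa5 in both genotypes, and Ddit3 and Eif2ak3 between genotypes in oil did pass (limma adjusted p from 0.000419 to 0.037). The pseudocount of 0.1 moved the median log2 value of all genes for the interaction to -0.14. Alternatives that need counts were not run because the values are FPKM, mitochondrial genes are not listed so their removal moves nothing, and the unknown depth limits what low values can show.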

Other observations

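The gene lists in this part were written only after the data were seen, so all their tests are of that kind. Their camera p-values were adjusted over these 4 lists alone, fewer than the lists set before the data were examined. The adjustment is therefore milder, and adjusted p-values here cannot be compared with those of the earlier lists. Calls close to the threshold, such as camera adjusted p = 0.0493 with an estimated correlation, rest on this smaller set. Genes known to be expressed more in male than in female mouse liver fell after CCl4 in wild-type hepatocytes, with 21 of 27 lower and 1 higher, and in knockout hepatocytes, with 20 lower and 3 higher. The male-predominant list had 1 higher and 23 lower adjusted over the list alone (camera adjusted p = 1.29e-23, and adjusted p = 0.00134 with an estimated correlation). For the male-predominant list, camera gave an adjusted p = 4.12e-05, and an adjusted p = 0.0310 with an estimated correlation, with 4 higher and 20 lower adjusted over the list alone. Between genotypes in oil, 15 were lower and 5 higher in the knockout, and after CCl4 the list did not pass, with 12 lower and 8 higher. The male-predominant list had 5 higher and 15 lower adjusted over the list alone (camera adjusted p = 0.000974, and adjusted p = 0.0493 with an estimated correlation). For the male-predominant list, camera gave an adjusted p = 0.362, and an adjusted p = 0.364 with an estimated correlation, with 9 higher and 13 lower adjusted over the list alone. Of 4 Y-linked genes tested, 1 was lower in the knockout in oil, or 2 adjusted over the list alone, and 3 were lower after CCl4, and none was higher. A difference in sex was therefore not told apart from genotype in these lists. Genes expressed more in female liver rose in wild-type hepatocytes after CCl4 in 8 of 15 cases and fell in 1. The female-predominant list had 8 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.000123, and adjusted p = 0.0257 with an estimated correlation). In knockout hepatocytes after CCl4, 4 rose and 5 fell, and between genotypes 9 were higher and 3 lower in the knockout in oil and 10 higher and 2 lower after CCl4. For the female-predominant list, camera gave an adjusted p = 0.866, and an adjusted p = 0.866 with an estimated correlation, with 4 higher and 5 lower adjusted over the list alone. The female-predominant list had 9 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.00523, and adjusted p = 0.0493 with an estimated correlation). For the female-predominant list, camera gave an adjusted p = 0.00302, and an adjusted p = 0.110 with an estimated correlation, with 10 higher and 2 lower adjusted over the list alone. The male list holds 10 Mup genes whose reads could be split between copies. Cyp2a4 and Cyp2a5, of which the former is the female-predominant copy, summed to 159.2 FPKM in wild-type oil, 48.8 in wild-type CCl4, 2166 in knockout oil and 4130 in knockout CCl4 hepatocytes. The direction between genotypes therefore holds for the sum, while the size of each copy's difference rests on how reads were divided between them. In wild-type hepatocytes after CCl4 the direction turned, with a log2 fold change of 3.18 for Cyp2a4 but -1.70 for the sum. A rise of Cyp2a4 is therefore uncertain there.

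Genes of fasting and gluconeogenesis were higher in knockout oil than in wild-type oil hepatocytes in 18 of 19 cases. The fasting list had 19 higher and 0 lower adjusted over the list alone (camera adjusted p = 8.58e-13, and adjusted p = 0.0493 with an estimated correlation). G6pc, which encodes glucose-6-phosphatase, stood at 604 ± 16.0 FPKM in knockout oil and 91.7 ± 6.20 FPKM in wild-type oil hepatocytes (SD, n = 2 each). Pck1, which encodes the gluconeogenic enzyme PEPCK, was at 2434 ± 115 and 905 ± 4.88 FPKM, and Igfbp1 at 614 ± 17.9 and 74.7 ± 4.91 FPKM. After CCl4, 12 of 19 were higher and 4 lower in the knockout. For the fasting list, camera gave an adjusted p = 0.00302, and an adjusted p = 0.296 with an estimated correlation, with 13 higher and 4 lower adjusted over the list alone. Clock genes and their targets fell after CCl4 in knockout hepatocytes in 12 of 19 cases and rose in 4, and for the interaction 10 were negative and 2 positive. The clock list had 4 higher and 12 lower adjusted over the list alone (camera adjusted p = 0.00916, and adjusted p = 0.383 with an estimated correlation). For the clock list, camera gave an adjusted p = 0.00963, and an adjusted p = 0.281 with an estimated correlation, with 3 positive and 10 negative adjusted over the list alone. The clock output gene Dbp was at 49.1 ± 9.10 FPKM in knockout oil and 8.02 ± 0.573 FPKM in knockout CCl4 hepatocytes (SD, n = 2 each). Feeding state and time of day are not given in the sources used here.

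The Y-linked gene Ddx3y was at 3.55 and 1.25 FPKM in replicates 1 and 2 of the knockout CCl4 group and 4.35 and 0.85 FPKM in those of the knockout oil group, against 8.17 to 8.85 FPKM in the 4 wild-type libraries, and Xist is not listed in the table. The symbols of 23 genes had been turned into dates, and these genes were followed by their Entrez identifiers.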
